A study of Mus musculus with 8 samples.

How the data were processed

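Nuclei of whole livers from 8 male mice, 4 aged 23 months and 4 aged 5 months, were profiled by droplet-based single-nucleus RNA sequencing, with 1 library per liver. Per the labels' protocols, nuclei were isolated, cleaned and sorted by flow cytometry, and libraries were made with the Chromium HT 3′ kit. The deposited matrices hold raw UMI counts per gene and barcode without normalization, made with Cell Ranger 7.1.0 per the file headers and with genome build mm10 per the submitters' processing notes. Neither source states the annotation release, the treatment of intronic reads or the settings for calling cells. Deposited totals ranged from 885375 UMIs in 9482 barcodes (old replicate 3) to 21874077 UMIs in 25102 barcodes (old replicate 4).

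Nuclei were kept with at least 300 detected genes and at most 5% mitochondrial counts. Scrublet in scanpy 1.11.5 set its own doublet limit at 0 to 6 barcodes per library that passed these filters, too few to have worked, and gave none for old replicate 3. Doublets were therefore removed by a fixed rate, the highest-scoring 0.4% per 1000 nuclei. Kept nuclei of all libraries were clustered together without batch integration by the Leiden algorithm (leidenalg 0.10.2) at resolution 1.0. A cluster was named after a class when at least 2 of the class's markers stood among its top 10 genes by fold and at least 3 were 2-fold higher than in the other nuclei. Clusters led by no other class and not by unnamed gene models were counted as hepatocyte-like. Most hepatocyte-like clusters drew chiefly on 1 or 2 libraries, so different clusters hold most of this class in the 2 ages. These naming details were set after the data were seen. A panel of 173 genes, at least 50 CPM in hepatocyte-like nuclei and at least 3 times lower in the 3 purest other clusters, measured hepatocyte RNA per barcode.

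Raw counts were summed per library and class, and libraries with at least 20 nuclei of the class were tested, so that the library is the replicate. Old replicate 3 kept 149 nuclei and entered only the whole-liver sums. All class comparisons therefore set 3 old against 4 young libraries. Genes were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3, TMM factors, filterByExpr, age as the only term), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. CPM values are normalized by the TMM factors, except in the interferon comparison between classes. That comparison used library size only, with a prior count of 2 and, as an alternative, 0.5. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The 31 gene lists were tested with camera (limma 3.58.1) at the preset correlation of 0.01, beside camera with an estimated correlation and fry. Shares of nuclei were compared by two-sided exact permutation tests over libraries with at least 500 kept nuclei. Values for 3 old and 4 young libraries allow 35 arrangements, with a smallest p of 0.0286.

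The design, the marker sets, the gene lists, the named-gene rule and the listed settings to vary were fixed before the data were examined. Named genes had an adjusted p under 0.05, a mean of at least 10 CPM and no overlap between the ages. The 8 with the largest log2 change in each direction were taken for hepatocyte-like nuclei and 5 for each other class, leaving out unnamed models. Up to 4 members with the smallest p were named for each list called by camera, and Stat2, Irf7, Isg15, Ifit1, Ifit3, Cdkn1a and Cdkn2a wherever measured. Another gene of this fixed set is not reported here. Cdkn2a passed the count filter in no class. Coordinates come from GENCODE vM21 (GRCm38, the mm10 assembly), which held 99.8% of the 13053 gene IDs tested. Values of the Mup, Cyp2c, Cyp2d, Ces3, Oas1 and H2-Q families are uncertain, because near-identical copies may share reads, as are those of Erdr1. Tymp and Sco2 overlap on the same strand, and so do Igtp and Irgm2, so their reads may be divided between them. The same limit holds for Manf, Podn and Hsd3b7, which overlap Rbm15b, Scp2 and Gm49388 on the same strand.

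After the data were seen, a further set of hepatocyte-poor barcodes was formed, because nuclei of the other classes held much hepatocyte RNA. It took barcodes with at least 100 genes, a panel share at most 0.5 times that of hepatocyte-like nuclei, and at least 3 marker UMIs of 1 class and 2 times those of the next. The selecting markers and the hepatocyte panel were left out of its tests. Endothelial-like, Kupffer and macrophage-like and stellate-like barcodes were numerous enough to test. The interaction test fitted library, class and class by age to the hepatocyte-like and endothelial-like sums in edgeR.

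The tests were checked on simulated data drawn from the real means and library sizes. For hepatocyte-like nuclei (12476 genes), edgeR recovered 39 of 100 genes changed by 1 on the log2 scale and 90 of 100 changed by 2, with 7 unchanged genes called. DESeq2 recovered 50 and 92, with 27 unchanged genes called. For endothelial-like nuclei (8460 genes) edgeR recovered 48 and 92, with 12 unchanged genes called, and for stellate-like nuclei (7831 genes) 47 and 92, with 8. The interaction test (8444 genes) recovered 6 of 76 and 51 of 62, with 7 unchanged genes called. Camera called 1 of 1 changed list, in which every gene was raised, and 0 of 30 unchanged lists. Its power for lists with few changed genes was not tested. The simulated genes varied independently, so this check cannot show false list calls that come from correlation between genes.

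Alternatives were DESeq2 1.42.0, scaling by library size only, no low-count filter, replicate number as a block, genes per nucleus as a covariate, sums thinned to 1 depth, at least 500 genes, at most 1% mitochondrial counts, doublets kept, clustering resolution 2.0, removal of genes that free RNA could bring in, and leaving out each library. Shares were also taken outside the hepatocyte class and on the logit scale. Alternatives added after the data were seen were counting the unnamed cluster as hepatocyte-like, leaving out the hepatocyte-like cluster led by Cxcl10 and Rsad2, nuclei of 400 to 1000 UMIs, leaving out the 2 libraries with fewest nuclei, and the hepatocyte-poor barcodes.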

Results

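Single-nucleus transcriptomes were collected from whole livers of male mice at 2 ages, 23 months (old, n = 4) and 5 months (young, n = 4). Total counts per library were 14918468, 16472887, 885375 and 21874077 UMIs in old replicates 1 to 4 and 9578415, 16088326, 16219251 and 19146357 UMIs in young replicates 1 to 4. After filtering, 12899, 15794, 149 and 16483 nuclei were kept in the old libraries and 7421, 16550, 16500 and 16631 in the young ones. Median UMIs per nucleus were 788, 648, 478 and 795 in old and 502, 630, 544 and 494 in young libraries. Ribosomal protein genes took 3.05% of the UMIs of kept nuclei in old replicate 3 and 0.187% to 0.337% in the other 7 libraries.

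Clusters were named endothelial-like, Kupffer and macrophage-like, stellate-like, T and NK-like, B-like and cholangiocyte-like from fixed markers. Those led by no other class and not by unnamed gene models were counted as hepatocyte-like, without use of hepatocyte markers. A cluster led by AY036118, Hist1h1e and unnamed gene models stayed unnamed and held 60.0% of the kept nuclei of young replicate 1, 85.9% of old replicate 3 and 0.132% to 1.18% of the others. Nuclei of the non-hepatocyte classes carried much hepatocyte RNA. In young replicate 2, for example, the median share of a 173-gene hepatocyte panel in endothelial-like nuclei was 0.817 times that in hepatocyte-like nuclei, and in stellate-like nuclei 0.737 times. In barcodes with fewer genes that were selected as hepatocyte-poor, the ratios in that library were 0.0848 for endothelial-like and 0.0695 for stellate-like barcodes. These were the lowest of the tested libraries, and the highest were 0.262 and 0.199, both in young replicate 4.

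**Figure D1:**
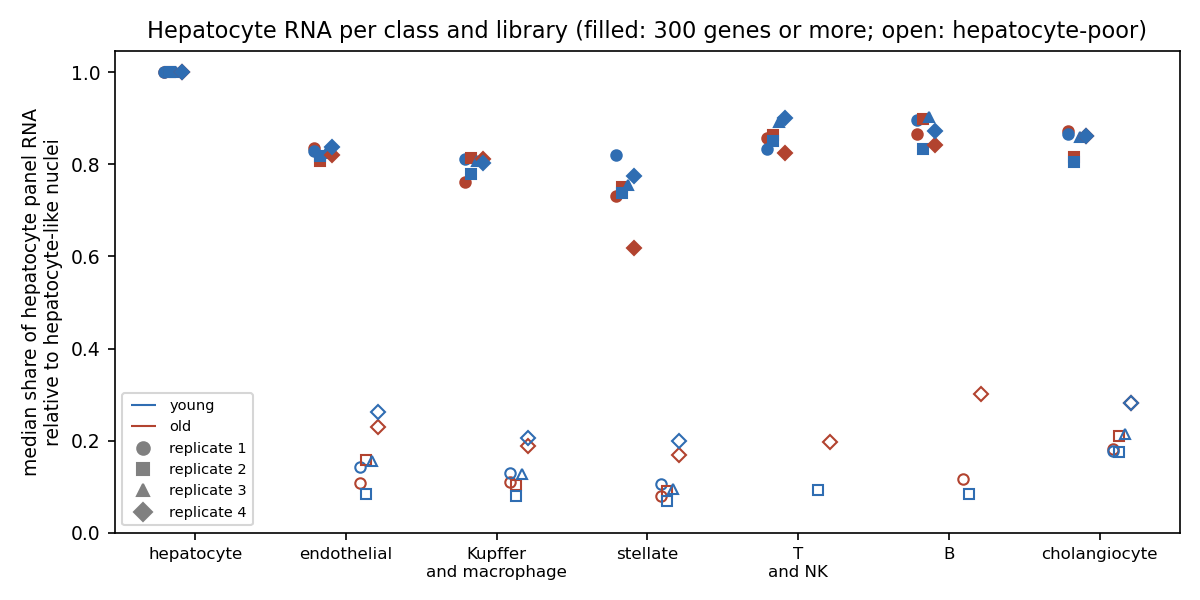
Median share of hepatocyte panel RNA per class and library, relative to hepatocyte-like nuclei of the same library (y axis, ratio), for classes with at least 20 barcodes. Filled points are nuclei with at least 300 genes and open points are hepatocyte-poor barcodes. In young replicate 2 the ratio for endothelial-like nuclei is 0.817 when filled and 0.0848 when open, the lowest open value of that class. In young replicate 4 the open value is 0.262.

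The main comparison asked which transcripts differ between old and young hepatocyte-like nuclei. Transcripts of Pcdh11x, a protocadherin gene, averaged 356 ± 186 CPM in old and 38.6 ± 11.2 CPM in young libraries (SD, n = 3 and 4). Mapt, which encodes the microtubule-binding protein tau, averaged 30.1 ± 7.85 CPM in old and 3.46 ± 1.81 CPM in young libraries, and Fgfr1, a receptor for fibroblast growth factors, 71.1 ± 40.0 and 10.0 ± 1.08 CPM. Cyp8b1, the sterol 12-alpha-hydroxylase of bile acid synthesis, averaged 23.3 ± 5.26 CPM in old and 121 ± 40.4 CPM in young libraries. G0s2, an inhibitor of triglyceride lipolysis, averaged 92.3 ± 25.1 and 429 ± 85.1 CPM.

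By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 233 genes rose and 157 fell with age among 12476 tested in hepatocyte-like nuclei (3 old and 4 young libraries). Old libraries held more UMIs per nucleus, and 0 genes passed with genes per nucleus as covariate. Median genes per hepatocyte-like nucleus did not overlap between the ages (468 to 590 in old and 379 to 466 in young libraries). This covariate therefore cannot be well separated from age. In sums thinned to 1 depth 118 of 8356 genes passed, but this thinning evens total counts and not UMIs per nucleus. Of the 390 genes, 387 showed no overlap between the ages, as did 20.2% of all genes tested, where chance gives 5.71%. The log2 fold changes were 3.18 ± 0.39 (SE) for Pcdh11x (adjusted p = 0.00809), 3.05 ± 0.34 for Mapt (adjusted p = 0.00786) and 2.80 ± 0.34 for Fgfr1 (adjusted p = 0.00786). They were -2.36 ± 0.29 for Cyp8b1 and -2.22 ± 0.24 for G0s2, each with an adjusted p of 0.00786. Pcdh11x (ENSMUSG00000034755) lies on chromosome X at 120290259 to 120910619, Mapt (ENSMUSG00000018411) on chromosome 11 at 104231390 to 104332090 and Fgfr1 (ENSMUSG00000031565) on chromosome 8 at 25513654 to 25575718 (mm10, protein-coding genes). Cyp8b1 (ENSMUSG00000050445) lies on chromosome 9 at 121914356 to 121916305 and G0s2 (ENSMUSG00000009633) on chromosome 1 at 193272161 to 193273217.

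The other genes named by rule as rising were Alpk1, an innate immune kinase that senses bacterial sugars (2.96 ± 0.40), Nebl (2.87 ± 0.45), Rad51b of homologous recombination (2.86 ± 0.38), the collagen gene Col25a1 (2.81 ± 0.53) and the B cell adaptor gene Blnk (2.77 ± 0.41), all as log2 fold change with SE. B cell markers also stood higher in these sums, as given below, so Blnk cannot be credited to hepatocytes alone. The genes named as falling were Mup17 (-3.83 ± 0.41) and Mup1 (-2.50 ± 0.50) of the major urinary proteins, Tymp (-2.30 ± 0.50), the fatty acid elongase gene Elovl3 (-2.23 ± 0.41), and Manf (-2.19 ± 0.36) and Creld2 (-2.08 ± 0.43), both induced by stress of the endoplasmic reticulum. All 49 named genes past the threshold kept their sign when any library was left out, and 6 of them kept their call each time, namely Pcdh11x, Mapt, Fgfr1, Cyp8b1, G0s2 and Mup17. The count was 89 without old replicate 1, 16 without old replicate 2, 91 without old replicate 4, 55 without young replicate 2, 238 without young replicate 3 and 215 without young replicate 4.

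**Figure D2:**
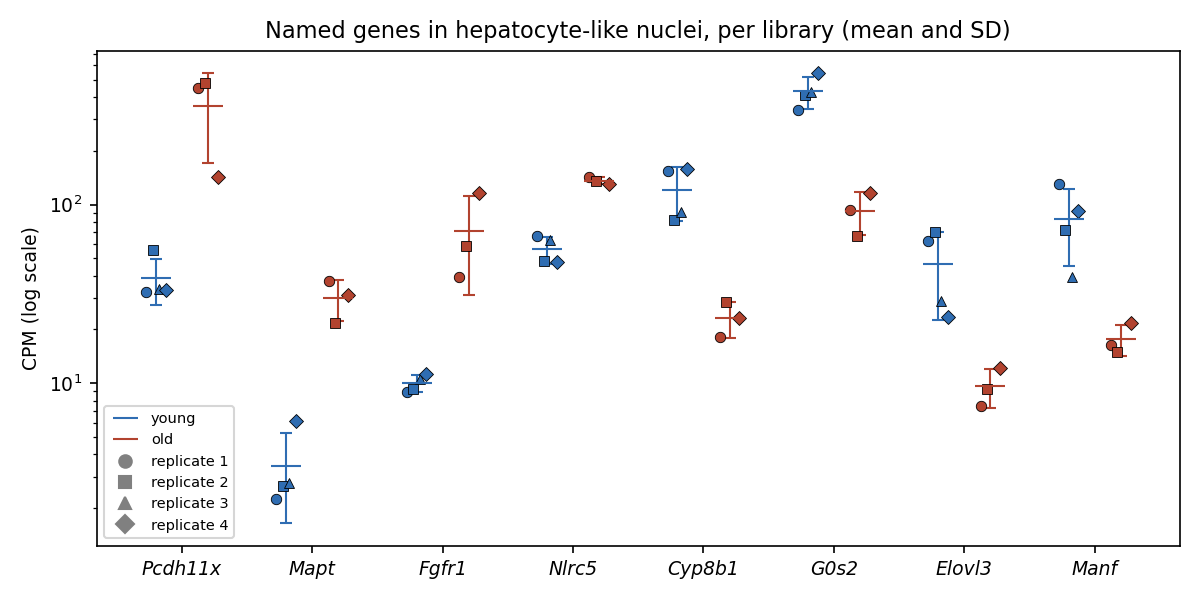
CPM (log scale) of 8 named genes in hepatocyte-like nuclei of each library, 3 old and 4 young. Points are libraries, horizontal marks the means and bars the SD; Mapt averages 30.1 CPM in old and 3.46 CPM in young libraries, and Manf 17.6 and 83.5 CPM.

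Genes of antigen presentation and the interferon gamma response stood higher in old hepatocyte-like nuclei. Of 37 measured members, 8 rose and 0 fell over all genes tested, and 28 rose when adjusted over the list alone. Nlrc5, a transactivator of MHC class I genes, rose from 56.2 ± 9.80 to 136 ± 6.34 CPM (log2 fold change 1.29 ± 0.16), the class I gene H2-Q4 from 16.6 ± 2.70 to 42.7 ± 8.82 CPM and Igtp, an interferon-induced GTPase gene, from 6.26 ± 1.54 to 18.4 ± 4.61 CPM. The class II gene H2-Aa rose by 2.40 ± 0.43 on the log2 scale, at a mean of 4.78 CPM in old libraries. The list's median log2 fold change was 1.20 and camera called it higher (adjusted p = 1.64e-19; adjusted p = 0.0634 with an estimated correlation). Markers of several other cell types stood higher in the same sums, with a median log2 fold change of 1.41 over 9 B cell markers, 0.96 over 10 T and NK markers, 0.84 over 18 Kupffer and macrophage markers and 0.66 over 26 endothelial markers. Of these, 2, 1, 1 and 1 passed the threshold. Stellate (-0.17 over 14), plasma cell (-0.40 over 4) and erythroid markers (-0.80 over 4) stood lower, with 0 past the threshold. Hepatocyte markers also stood lower (-0.22 over 20), with 2 past the threshold and a summed CPM of 29140 in old and 34678 in young libraries. The summed CPM of the T and NK markers lay the other way, at 446 in old and 568 in young libraries, while that of the B cell markers was 138 and 81.8.

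Genes of the type I interferon response also stood higher as a list in old hepatocyte-like nuclei. Of 41 measured members, 5 rose and 0 fell over all genes tested, and 14 rose when adjusted over the list alone. The median log2 fold change was 0.45 and camera called the list higher (adjusted p = 1.81e-07; adjusted p = 0.0970 with an estimated correlation). Zbp1, a nucleic acid sensor, rose by 2.54 ± 0.35 on the log2 scale, Xaf1 by 1.72 ± 0.33, Trim30a by 1.33 ± 0.24 and Oas1a, at 2.18 CPM in old libraries, by 2.33 ± 0.47. The log2 fold changes were 0.40 ± 0.20 for Stat2, 0.58 ± 0.26 for Irf7, 0.47 ± 0.46 for Isg15, 0.01 ± 0.32 for Ifit1, -0.29 ± 0.59 for Ifit3 and -0.84 ± 0.51 for Cdkn1a, and none passed the threshold.

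Genes of the unfolded protein response stood lower in old hepatocyte-like nuclei. Of 20 measured members, 9 fell and 0 rose over all genes tested, and 14 fell when adjusted over the list alone. Hspa5, the main chaperone of the endoplasmic reticulum, fell from 155 ± 39.2 to 46.3 ± 16.7 CPM, the disulfide isomerase gene Pdia4 from 134 ± 16.4 to 51.4 ± 7.70 CPM, Manf from 83.5 ± 38.1 to 17.6 ± 3.49 CPM and Sel1l, a component of protein degradation at that organelle, from 409 ± 34.1 to 239 ± 13.6 CPM. The median log2 fold change was -0.99 and camera called the list lower (adjusted p = 1.41e-14; adjusted p = 0.110 with an estimated correlation). The camera calls of these 3 lists held when any library was left out.

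**Figure D3:**
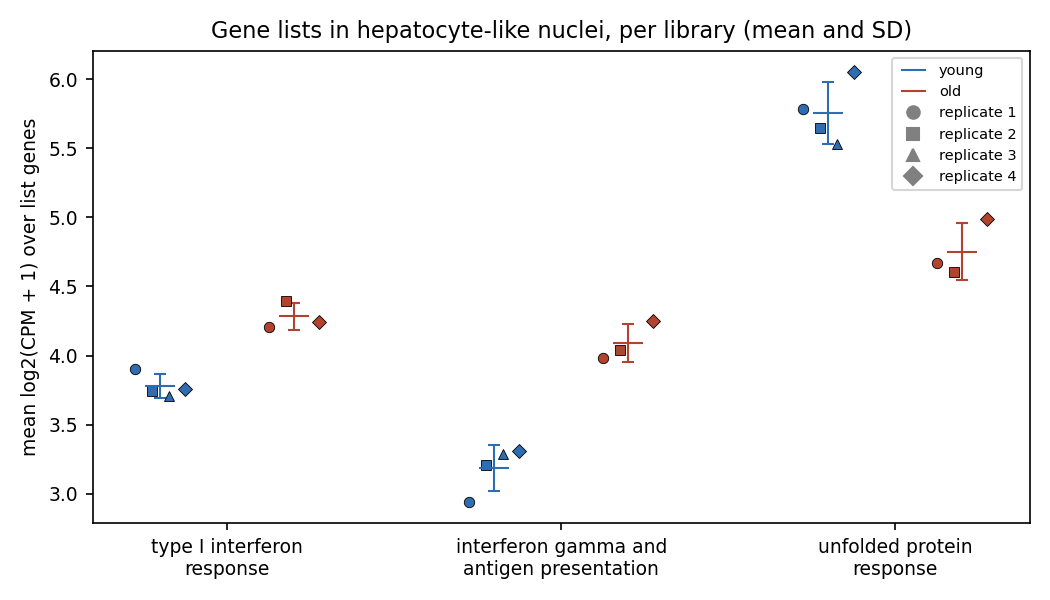
Mean log2(CPM + 1) over the measured genes of 3 lists in hepatocyte-like nuclei of each library. Points are libraries, horizontal marks the group means and bars the SD; the unfolded protein response list averages 4.75 in old (n = 3) and 5.75 in young (n = 4) libraries, and the antigen presentation list 4.09 and 3.19.

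Several lists of lipid and drug metabolism were called lower in old hepatocyte-like nuclei. Of 28 genes of fatty acid oxidation and PPARalpha targets, 3 fell (Angptl4, Pex11a and Vnn1) and 0 rose, and 11 fell when adjusted over the list alone (median log2 fold change -0.52; camera adjusted p = 4.78e-06; adjusted p = 0.278 with an estimated correlation). Of 19 genes of lipid droplets and lipid uptake, 4 fell (G0s2, Fabp2, Plin2 and Fitm1), and 4 fell and 2 rose when adjusted over the list alone (median -0.48; adjusted p = 0.00187; adjusted p = 0.316 with an estimated correlation). Of 19 genes of bile acid synthesis and transport, 2 fell (Cyp8b1 and Hsd3b7), and 3 fell when adjusted over the list alone (median -0.30; adjusted p = 0.00168; adjusted p = 0.266 with an estimated correlation). Of 36 drug-metabolising enzymes, 4 fell, among them Cyp2c29, Ces3a and the nuclear receptor gene Nr1i3, and 6 fell and 1 rose when adjusted over the list alone (median -0.36; adjusted p = 0.00125; adjusted p = 0.278 with an estimated correlation). Of 22 male-biased liver genes, 4 fell (Elovl3, Cyp2d9, Mup21 and Mup12), and 8 fell when adjusted over the list alone (median -0.09; adjusted p = 0.0220; adjusted p = 0.462 with an estimated correlation). The camera call of male-biased genes was lost without old replicate 1 or without young replicate 3, and its median ranged from -0.21 to 0.01 over the 7 cases.

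Of 24 genes of cholesterol synthesis, 2 rose (Cyp51 and Hsd17b7), and 7 rose and 1 fell when adjusted over the list alone (median log2 fold change 0.32; camera adjusted p = 1.90e-04, higher; adjusted p = 0.458 with an estimated correlation). Of 15 NF-kB targets, 3 rose (the adhesion gene Icam1 and the NF-kB subunit genes Relb and Rel), and 3 rose when adjusted over the list alone (median 0.54; adjusted p = 3.95e-05, higher; adjusted p = 0.114 with an estimated correlation). Of 13 cytokine and chemokine genes 1 rose (Tnfsf10), and 3 rose and 1 fell when adjusted over the list alone (median 0.81; adjusted p = 0.0102, higher; adjusted p = 0.458 with an estimated correlation). Of 7 fetal liver and tumour markers 1 rose (Robo1), and 3 when adjusted over the list alone (median 0.70; adjusted p = 0.0220, higher; adjusted p = 0.278 with an estimated correlation). Of 18 genes of sinusoidal endothelial identity 1 rose (the clotting factor gene F8), and 1 when adjusted over the list alone (median 0.39; adjusted p = 0.0196, higher; adjusted p = 0.716 with an estimated correlation). Endothelial markers stood higher in the same sums (median 0.66 over 26), so this list cannot be credited to hepatocytes. Markers of several immune classes stood higher there too, as given above, so the NF-kB and cytokine lists cannot be credited to hepatocytes alone. The call of cytokines was lost without young replicate 2 or old replicate 4, that of fetal and tumour markers without young replicate 3, old replicate 4 or young replicate 4, and that of sinusoidal genes without old replicate 1, young replicate 2 or young replicate 3. With 1 library left out, medians ranged from 0.29 to 0.64 for NF-kB targets, 0.25 to 0.55 for cholesterol synthesis, 0.27 to 1.03 for sinusoidal genes, -0.50 to -0.18 for bile acid genes and -0.59 to -0.35 for fatty acid oxidation. The other 18 lists were not called (adjusted p from 0.0553 to 0.859). They covered interferon receptors, acute phase, complement, p53 targets and senescence, cell cycle, fatty acid synthesis, glucose and insulin signalling, female-biased genes, circadian clock, pericentral and periportal genes, heat shock, NRF2 targets, extracellular matrix, capillary endothelium, resident Kupffer genes, recruited macrophages and quiescent stellate genes.

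Many genes past the threshold in the non-hepatocyte classes were also called in hepatocyte-like nuclei in the same direction. In endothelial-like nuclei, 24 genes rose and 18 fell among 8460 (14 and 34 in sums thinned to 1 depth), and 40 of these 42 were shared, where independent lists would share 0.686. In Kupffer and macrophage-like nuclei, 18 rose and 32 fell among 6051, of which 35 were shared (0.809 for independent lists). In stellate-like nuclei, 77 rose and 66 fell among 7831; of the 126 also tested in hepatocyte-like nuclei, 71 were shared (2.09 for independent lists). In T and NK-like nuclei, 7 rose and 17 fell among 3381, of which 15 were shared, and in B-like nuclei 6 rose and 14 fell among 3213, of which 14 were shared. In cholangiocyte-like nuclei, 1 rose (Noct) and 4 fell among 1535, of which 3 were shared. All classes come from the same libraries and hold hepatocyte RNA, as given above.

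Genes named in these classes included markers of the class itself. In Kupffer and macrophage-like nuclei, the lectin gene Clec4f fell from 268 to 103 CPM (log2 fold change -1.38 ± 0.19) and the scavenger receptor gene Cd163 from 64.8 to 11.4 CPM (-2.56 ± 0.46). Of 9 resident Kupffer genes 2 fell, and 4 fell when adjusted over the list alone (median -0.40; camera adjusted p = 4.61e-07, lower; adjusted p = 0.355 with an estimated correlation). Clec4f and Cd163 were among the selecting markers, so they were not tested in hepatocyte-poor barcodes. At resolution 2.0, 1762 of the 1820 barcodes of a cluster of mixed markers came from old replicate 4. A smaller part of Kupffer RNA in the old sums is therefore not excluded. In stellate-like nuclei, Wt1, a transcription factor gene of the stellate and mesothelial lineages, rose from 2.28 to 34.7 CPM (3.54 ± 0.50), the collagen receptor gene Mrc2 from 6.69 to 35.5 CPM (2.36 ± 0.39), Col3a1 from 32.6 to 82.7 CPM (1.37 ± 0.29) and Col6a3 from 35.3 to 96.6 CPM (1.49 ± 0.33). Of 17 genes of extracellular matrix and fibrosis 2 rose, and 3 rose when adjusted over the list alone (median 0.27; camera adjusted p = 0.00686, higher; adjusted p = 0.485 with an estimated correlation). The call of Cd163 was lost without young replicate 2 or old replicate 4, that of Wt1 without old replicate 2, that of Mrc2 without old replicate 2 or 4, and that of Col3a1 without old replicate 2, old replicate 4 or young replicate 4. Col6a3 lost its call in these 3 cases and without young replicate 2. Without old replicate 2, the counts were 2 in endothelial-like, 18 in Kupffer and macrophage-like and 3 in stellate-like nuclei.

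In hepatocyte-poor stellate-like barcodes, Wt1 rose from 14.1 to 129 CPM (log2 fold change 2.77 ± 0.49, edgeR adjusted p = 0.00640), and its call held when any library was left out. In all, 48 genes rose and 26 fell among 4039 tested there, 18 without old replicate 2, 177 without young replicate 2 (66 higher and 111 lower), 27 without young replicate 3, 36 without old replicate 1 and 32 without young replicate 4. Scube1 rose by 2.55 ± 0.55, Erdr1 by 2.03 ± 0.30, the proteoglycan gene Podn by 1.88 ± 0.45 and Plcxd3 by 1.85 ± 0.40 on the log2 scale. Mup17 fell by 2.40, the netrin receptor gene Dcc by 2.15, the natriuretic peptide receptor gene Npr3 by 2.04, Cdh13 by 1.85 and Zbtb16 by 1.70. Of these 9 genes, Erdr1 kept its call when any library was left out. Zbtb16 (-1.95 to -0.73), Cdh13 (-2.16 to -1.25) and Podn (1.60 to 2.09) lost it in 6 of 7 cases, Scube1 and Plcxd3 in 4, Mup17 without old replicate 2 or young replicate 3, and Dcc and Npr3 without old replicate 2. Of 54 called genes that were also tested in hepatocyte-like nuclei, 11 were shared (0.946 for independent lists). In hepatocyte-poor endothelial-like barcodes, edgeR called 0 of 3613 genes (209 at an unadjusted p under 0.05), and DESeq2 called 4. In hepatocyte-poor Kupffer and macrophage-like barcodes, edgeR called 0 of 512 genes (41 at an unadjusted p under 0.05), and DESeq2 called 0 of 511 (22 at an unadjusted p under 0.05). The antigen presentation list was called higher in hepatocyte-poor endothelial-like barcodes (9 genes, median log2 fold change 0.63, 0 past the threshold and 2 when adjusted over the list alone; camera adjusted p = 9.74e-08; adjusted p = 0.130 with an estimated correlation) and stellate-like barcodes (11 genes, median 0.47, 1 past the threshold and 2 when adjusted over the list alone; adjusted p = 0.00161; adjusted p = 0.214 with an estimated correlation). The unfolded protein response list (7 genes in each) was called lower in both, with medians of -0.97 (0 past the threshold, 6 when adjusted over the list alone; adjusted p = 5.49e-09; adjusted p = 0.130 with an estimated correlation) and -0.82 (3 past the threshold, 4 when adjusted over the list alone; adjusted p = 1.68e-06; adjusted p = 0.214 with an estimated correlation).

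In whole-liver sums of all 8 libraries, 12 genes rose and 11 fell among 12922, and all 23 were also called in hepatocyte-like nuclei in the same direction. Noct, a circadian gene of NADPH metabolism, rose by 2.71 ± 0.43 on the log2 scale, and Rad51b, Fgfr1, Blnk, Alpk1 and Zbp1 rose as well. Mup17 (-3.56 ± 0.43), Hspa5 (-1.67 ± 0.28), Cyp2d40 (-1.62 ± 0.22), Sco2 (-1.60 ± 0.25), Lppos (-1.59 ± 0.22) and Pdia4 (-1.42 ± 0.19) fell. Old replicate 3 gave 149 of the nuclei, and without it 141 genes passed. The count was 2 without old replicate 1, 0 without old replicate 2, 1 without old replicate 4, 0 without young replicate 2 or 4 and 7 without young replicate 3.

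No class share passed the exact permutation test after adjustment (3 old and 4 young libraries), a test in which 1 class alone at the smallest p of 0.0286 would adjust to 0.2 over 7 classes. Endothelial-like nuclei made up 5.96 ± 0.574% of kept nuclei in old and 10.5 ± 4.65% in young libraries (exact permutation p = 0.0857, adjusted p = 0.4). Young replicate 4 stood at 17.4% and the other young libraries at 7.28% to 9.10%, and without it the young mean was 8.23 ± 0.914%. B-like nuclei made up 1.71 ± 0.611% and 0.963 ± 0.410% (exact permutation p = 0.114, adjusted p = 0.4). Kupffer and macrophage-like nuclei made up 8.57 ± 9.04% and 3.08 ± 1.64% (exact permutation p = 0.200, adjusted p = 0.467). The old mean rests on old replicate 4, with 18.995% against 2.86% and 3.86% in old replicates 1 and 2, and without it the shares were 3.36 ± 0.704% and 3.08 ± 1.64%. At resolution 2.0, 1762 of the 1820 barcodes of a cluster of mixed markers, counted before doublets were removed, came from old replicate 4. As a share of nuclei outside the hepatocyte class, Kupffer and macrophage-like nuclei made up 30.4 ± 18.2% in old and 10.96 ± 5.75% in young libraries (exact permutation p = 0.0286, adjusted p = 0.171). Old replicate 4 stood at 51.4%, and the old mean without it was 19.8 ± 0.962% (n = 2). Young replicate 1 stood at 2.40%, with the unnamed cluster in the denominator, and the other young libraries at 12.97% to 14.6%. The adjusted p of the remaining classes lay between 0.533 and 0.629. The nuclei had been flow-sorted and filtered at 300 genes, and the unnamed cluster took 60.0% of young replicate 1, so these shares are of kept nuclei only.

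The age difference of the type I interferon list was compared between hepatocyte-like nuclei and each other class within libraries. The mean log2 CPM of its 48 genes was 0.53 higher in old hepatocyte-like nuclei and 0.42 higher in old endothelial-like nuclei, and the difference of 0.12 did not pass (exact permutation p = 0.371, adjusted p = 0.557). Differences to the other 5 classes lay between 0.15 and 0.35 with adjusted p from 0.514 to 0.657 by exact permutation. With a prior count of 0.5 in place of 2 they lay between 0.05 and 0.30, with 0.09 for B-like and 0.12 for cholangiocyte-like nuclei. A larger prior count flattens changes more in classes with fewer counts. Endothelial-like nuclei held much hepatocyte RNA (in young replicate 2, 0.817 times the panel share of hepatocyte-like nuclei), and so did the other classes. The comparison thus sets hepatocyte RNA partly against itself. A small difference therefore does not show a similar rise in the other cells. Without young replicate 1, the difference was 0.21 to endothelial-like, 0.42 to Kupffer and macrophage-like, 0.32 to stellate-like, 0.53 to T and NK-like, 0.46 to B-like and 0.42 to cholangiocyte-like nuclei, each with an exact permutation p of 0.1, the smallest that 3 old and 3 young libraries allow. In edgeR's test of the class by age term, 40 of 10661 genes changed differently with age in hepatocyte-like and endothelial-like nuclei, 37 with the larger log2 change in hepatocyte-like nuclei. Another split of the libraries gave 196 genes, so chance is not excluded for this count. Rarg, a retinoic acid receptor gene, differed by 2.43 ± 0.33 and the growth factor gene Pdgfd by 1.78 ± 0.28 on the log2 scale, both chosen after their values were seen. The called genes also include 3 endothelial markers of the fixed set, Stab2 (1.08 ± 0.21), Plekhg1 (1.05 ± 0.23) and Ptprb (1.04 ± 0.23), as well as Mrc1 (1.10 ± 0.22) and Eng (1.08 ± 0.25) of sinusoidal endothelium, chosen in the same way. In the hepatocyte-like sums, endothelial markers stood higher in old libraries by a median log2 fold change of 0.66. The count was 5 without old replicate 4, 12 without young replicate 2, 17 without young replicate 3, 24 without old replicate 1 and 205 without young replicate 4.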

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

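Of the tests reported in this part, those on RNA of other cell types were chosen after the marker values had been seen, and the criteria of the other tests were written before their values were computed. Among 195 groups of 4 libraries examined for 1 library far from the others, 16 stood out by Dixon's ratio, and chance gives about 5% of groups.

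Young replicate 1 kept 7421 nuclei, far from the other young libraries. Old replicate 3 had 3.05% of its UMIs in ribosomal protein genes. The unnamed cluster held 85.9% of the kept nuclei of old replicate 3 and 60.0% of those of young replicate 1, each far from the other libraries of its age. In hepatocyte-like nuclei, Mapt stood at 6.15 CPM in young replicate 4, Pcdh11x at 55.4 CPM in young replicate 2 and Alpk1 at 4.03 CPM in young replicate 2. In whole-liver sums, Zbp1 was listed at 0 CPM in old replicate 3 and Rad51b stood at 45.8 CPM in young replicate 3. G0s2 stood at 399.952 CPM in endothelial-like nuclei of young replicate 4, and Setbp1 was listed at 0 CPM in Kupffer and macrophage-like nuclei of young replicate 1. In stellate-like nuclei, Hsd3b5 stood at 72.4 CPM in young replicate 3 and Cyp2d9 at 698 CPM in young replicate 4. In hepatocyte-poor stellate-like barcodes, Npr3 stood at 193 CPM and Herpud1 at 80.4 CPM in young replicate 3, and Zbtb16 at 1374 CPM in young replicate 2. By the class by age term, 40 genes changed differently with age in hepatocyte-like and endothelial-like nuclei, a count for which chance is not excluded.

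The antigen presentation list stood higher in old hepatocyte-like nuclei, by a median of 1.20 on the log2 scale. More UMIs per nucleus in old libraries are argued against as the whole cause, since the median was 0.97 in nuclei of 400 to 1000 UMIs. They may account for part, since that median is lower and the range may not even UMIs per nucleus. With genes per nucleus as covariate the median was 0.78 and the count of 390 genes went to 0. Values of that covariate did not overlap between the ages, so it cannot well separate UMIs per nucleus from age. In sums thinned to 1 depth the median was 0.76 and 118 genes passed. That setting evens total counts and not UMIs per nucleus, so it does not bear on this cause. RNA of other cell types may account for part of it, since B cell markers stood higher by a median of 1.41 in the same sums. Scaled from the marker rises of 6 other classes, such RNA would bring 80.9% of the rise of the median MHC class II gene and 35.5% of that of the median gene outside class II. Single class II genes ranged from 61.1% (H2-Aa) to 287% (Ciita), the latter more than its whole rise. The class sums hold hepatocyte RNA, which raises this estimate. T and NK cells enter it with 0 because their summed markers were lower in old libraries, which may lower it. The cause therefore stays open for class II genes and for the others.

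The unfolded protein response list stood lower in old hepatocyte-like nuclei, by a median of -0.99 on the log2 scale. More UMIs per nucleus in old libraries are argued against as the whole cause, since the median was -0.997 in nuclei of 400 to 1000 UMIs. That range limits UMIs per nucleus but may not even them. With genes per nucleus as covariate the median was -1.04, but that covariate cannot be well separated from age. In sums thinned to 1 depth, which evens total counts and not UMIs per nucleus, the median was -0.78. Livers taken at another time of day could lower such genes, and the contrast of clock genes of opposite phase differed by -1.49 between old and young (exact permutation p = 0.114, 3 old and 4 young libraries). Young replicate 4 had a clock contrast of -1.70, within the spread of the old libraries (-1.63, -1.65 and -1.82), and yet the highest list level of all, 6.05, but it is 1 library. Time of day and age cannot be told apart, because 3 of the 4 young libraries differ from the old ones in clock genes.

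Wt1 stood higher in old stellate-like barcodes poor in hepatocyte RNA, with 95 UMIs in 3 old libraries and 9 in 4 young ones. Mesothelial nuclei among these barcodes are not excluded: 6 other mesothelial markers together stood at 0.327 times their young level, but on 4 UMIs in old and 11 in young libraries (exact permutation p = 0.514, 3 old and 4 young libraries). Barcodes with Wt1 held a lower share of stellate marker UMIs in all 3 old libraries and in the 3 young ones that had any, as this explanation requires, but the selection on marker UMIs in shallow barcodes could give the same. The cause stays open.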

How the results depend on the processing

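The 13 lists called in hepatocyte-like nuclei kept camera's direction in every alternative, and their call in 230 of 273 cases. Camera with an estimated correlation called 0 lists and fry 6; all other settings called 10 to 16, and camera was not run on DESeq2. Single named genes kept direction and side of the threshold in 2324 cases, missed the threshold in 902 and changed sign in 19. The causes below were not tested.

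The count for hepatocyte-like nuclei (390) was 974 with DESeq2, 213 with library size only, 0 with genes per nucleus as covariate, 118 with sums thinned to 1 depth and 46 with the unnamed cluster included. The whole-liver count (23) was 71, 6 (2 higher, 4 lower), 1 and 0 in the first 4 of these settings, 64 with at least 500 genes and 115 without the 2 libraries with fewest nuclei, a setting chosen after seeing the data like the unnamed cluster and all hepatocyte-poor results. DESeq2 gave 147 in endothelial-like (64 higher, 83 lower), 10 in B-like (4 higher, 6 lower) and 4 in hepatocyte-poor endothelial-like sums. Library size only gave 42 in hepatocyte-poor stellate-like barcodes.

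The covariate gave 17 in endothelial-like, 6 in Kupffer and macrophage-like, 16 in stellate-like, 5 in T and NK-like, 3 in B-like, 0 in cholangiocyte-like and 1 in hepatocyte-poor stellate-like sums. Thinning gave 48 in endothelial-like (14 higher, 34 lower), 11 in Kupffer and macrophage-like, 79 in stellate-like, 15 in T and NK-like, 11 in B-like, 2 in cholangiocyte-like and 22 in hepatocyte-poor stellate-like sums. At least 500 genes gave 75 in stellate-like, 10 in T and NK-like, 8 in B-like and 2 in cholangiocyte-like nuclei. No count filter gave 358 in endothelial-like (151 higher, 207 lower), 318 in Kupffer and macrophage-like, 553 in stellate-like, 48 in T and NK-like, 41 in B-like and 22 in cholangiocyte-like nuclei, 18, 1 and 135 in hepatocyte-poor endothelial-like, Kupffer and macrophage-like and stellate-like barcodes, and 132 for the class by age term. Resolution 2.0 gave 31 in B-like and 11 in cholangiocyte-like nuclei and 15 for the class by age term, and keeping doublets 11 in cholangiocyte-like nuclei. For the class by age term, which holds library as a term, DESeq2, the covariate, thinning and the filter on free RNA were not run.

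Leaving out 1 library gave 16 to 582 in hepatocyte-like nuclei, 0 to 141 in whole-liver sums, 2 to 80 in endothelial-like, 18 to 58 in Kupffer and macrophage-like, 3 to 156 in stellate-like, 6 to 36 in T and NK-like, 5 to 17 in B-like and 1 to 14 in cholangiocyte-like nuclei. It gave 0 to 2, 0 to 3 and 18 to 177 in hepatocyte-poor endothelial-like, Kupffer and macrophage-like and stellate-like barcodes, and 5 to 205 for the class by age term.

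Whether the replicate numbers pair old and young livers stays open. Deviations of same-numbered hepatocyte-like sums correlated across genes at -0.00, 0.21 and 0.35. Old replicates 2 and 4 correlated best with the young library of the same number, but old replicate 1 with young replicate 2 (0.18). The replicate block gave 165 in hepatocyte-like nuclei, 0 in whole-liver sums, 209 in endothelial-like (85 higher, 124 lower), 131 in Kupffer and macrophage-like, 222 in stellate-like and 14 in cholangiocyte-like nuclei, 3 and 1 in hepatocyte-poor endothelial-like and Kupffer and macrophage-like barcodes, and 82 (41 higher, 41 lower) in stellate-like ones. It changed no other count by over 1.5 times. It called 13 lists, but only 11 of the 13 lists called without the block kept their call. Shares with 3 pairs allow no p under 0.25.

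No share passed by adjusted p in any setting. The stellate-like difference turned to 1.46 outside the hepatocyte class and ranged from -2.39 to 0.14 with 1 library left out, and the T and NK-like one to -0.0523 at 500 genes. The interferon list difference turned to -0.12 (endothelial-like) and -0.0180 (Kupffer and macrophage-like) with the median over genes and to -0.0219 (Kupffer and macrophage-like) at 500 genes. With a prior count of 0.5 it lay between 0.05 (Kupffer and macrophage-like) and 0.30 (T and NK-like). It rose to 0.21 to 0.53 over the 6 classes without young replicate 1, and none passed the threshold in these settings.

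Sign changes of named genes touched 3 uncalled genes. Ifit1 in hepatocyte-like nuclei stood at -0.0169 with library size only, -0.0862 with the block, -0.27 at 500 genes, -0.000784 with doublets kept, -0.12 at resolution 2.0, -0.33 in nuclei of 400 to 1000 UMIs and -0.12 to 0.16 with 1 library left out. Ifit3 there stood at 0.59 with the covariate, 0.0081 with the unnamed cluster, 0.0434 without the Cxcl10 and Rsad2 cluster and -0.62 to 0.17 with 1 library left out. Stat2 under the covariate stood at -0.12 in hepatocyte-like, -0.10 in Kupffer and macrophage-like and -0.13 in whole-liver sums, at -0.0308 in thinned hepatocyte-poor stellate-like sums, and at -0.0563 to 0.278 in Kupffer and macrophage-like nuclei with 1 library left out.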

Other observations

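The criteria of the tests in this part were written before their values were computed, but after the gene results had been seen for interferon transcripts per nucleus. Clock genes of opposite phase stood apart within the young group. The contrast of Arntl, Clock and Npas2 against Dbp, Tef, Nr1d1, Per1, Per2 and Per3 in hepatocyte-like nuclei was 0.97, -0.04, -0.08 and -1.70 in young replicates 1 to 4, and -1.63, -1.65 and -1.82 in old replicates 1, 2 and 4. The circadian clock list as a whole was not called (20 genes, 0 past the threshold; 5 rose and 2 fell when adjusted over the list alone).

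A hypothesis was that a larger share of old hepatocyte-like nuclei holds type I interferon transcripts. With each nucleus thinned to 300 UMIs, which left out 0 nuclei, 1.59 ± 0.505% of old and 0.901 ± 0.0286% of young nuclei held at least 3 UMIs of the list, a difference of 0.69 percentage points with no overlap (exact permutation p = 0.0286, the smallest that 3 old and 4 young libraries can give). Without thinning the shares were 17.3 ± 5.57% and 4.78 ± 1.65%. Endothelial-like nuclei held 1.68%, 2.49% and 3.31% in old replicates 1, 2 and 4 and 1.30% to 1.52% in young libraries at the same depth. A level of 3 UMIs in 300 lies near the floor, so although the criterion of no overlap was met, no change in the number of expressing nuclei is read from it. The hepatocyte-like cluster led by Cxcl10 and Rsad2, before doublets were removed, held 98, 165 and 155 of 13628, 16657 and 17576 nuclei in old replicates 1, 2 and 4. In young replicates 1 to 4 it held 11, 89, 58 and 30 of 7653, 17468, 17482 and 17540. Clustering did not even UMIs per nucleus, which were higher in old libraries, so these values do not settle the hypothesis.

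Other splits of the 7 libraries into groups of 3 and 4 (35 splits) were run for each gene count. For hepatocyte-like nuclei 1 of 35 splits, the real one, gave as many genes (390, highest other 0). This argues against chance but cannot exclude it, since chance alone puts the real split first in 1 of 35 cases. The same held in whole-liver sums (23, highest other 0), where all 8 libraries form 35 splits of 4 and 4, and in endothelial-like (42, highest other 5), Kupffer and macrophage-like (50, highest other 1), stellate-like (143, highest other 7), T and NK-like (24, highest other 6), B-like (20, highest other 5) and cholangiocyte-like nuclei (5, highest other 1). These counts come from the same libraries and share hepatocyte RNA, so they add no independent support. For hepatocyte-poor stellate-like barcodes the splits do not argue against chance, since 2 of 35 gave as many genes (74, highest other 77). For hepatocyte-poor endothelial-like (0, highest other 12) and Kupffer and macrophage-like barcodes (0, highest other 3) all 35 splits gave as many, which a count of 0 brings with it, so these splits test nothing. For the class by age term 2 of 35 splits gave as many genes (40, highest other 196), so chance is not excluded. The other split set young replicates 1, 2 and 3 against the rest, so it differs from the age split only in young replicate 4. Age itself gave 205 genes without that library, so this split cannot tell age from another structure of the libraries.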
